A study of Homo sapiens with 2 samples.

How the data were processed

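RNA was measured by poly(A)-selected sequencing on a DNA nanoball platform in 2 libraries from cells labelled as MDA-MB-231, a line established from a human triple-negative breast carcinoma. One library came from cells with a control short hairpin RNA (shCtrl) and the other from cells with a knockdown of ZEB1 (shZEB1), a zinc-finger repressor known for driving the epithelial-to-mesenchymal transition. The hairpin sequence, vector and strand setting of the counting were not given in the sources used here.

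Per the submitters' processing notes, the tools included HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and DESeq, with the hg38 genome. Their order and settings are not given in the sources used here. The deposited files held, per the file headers, an expected count (an estimated number of reads) and an FPKM value (fragments scaled to gene length and library total) for each gene, made by the authors for each library alone. Genes carried Entrez Gene identifiers, and their transcripts mixed RefSeq accessions with loci assembled by the authors. The deposited expected counts were whole, to the 2 decimals given, for 78.8% of shCtrl genes and 78.0% of shZEB1 genes, since reads matching several models are shared out by estimation. The FPKM values implied a total of 8682412 reads in shCtrl and 8396342 in shZEB1, close to the summed expected counts of 8740584 and 8441491. No gene was listed at 0 (lowest expected count 0.19 in shCtrl and 0.17 in shZEB1), so a gene missing from 1 file was entered at 0 and is described as not listed. Of 15217 numeric identifiers, 15183 were matched to symbols in the RefSeq annotation of GRCh38.p14, which also gave the coordinates. Assembled loci, which carried 2.92% of the shCtrl reads and 2.80% of the shZEB1 reads, were kept in library totals.

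With 1 library per group there was no test between the conditions and no p-value. The choices below were fixed before the data were examined, except where stated. The main measure was log2((FPKM shZEB1 + 1)/(FPKM shCtrl + 1)), which understates the difference for genes of low FPKM. Genes with FPKM of at least 1 in either library counted as measured. A gene was counted as higher or lower where this log2 ratio reached 1 or -1 and a 95% interval of its read ratio excluded a ratio of 1. That interval was the exact conditional binomial (Clopper-Pearson) interval on expected counts rounded to whole numbers, scaled by library totals. It covers counting error only, and takes reads as independent. Reads amplified by PCR without molecular identifiers are not independent molecules, so it may be too narrow even for that. Error from sharing reads between gene models is not in it, and the spread between cultures was not measured. Folds are ratios of FPKM and intervals are ratios of reads scaled to the library totals. The 2 can part where the gene length used by the authors differed between files.

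Each of 20 gene lists was described by its median log2 ratio and by the place of that median among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. Counting error of a list median was taken from 1000 Poisson draws of its members' counts. Genes of a list are not independent, so these places describe the 2 libraries. The genes named were ZEB1, ZEB2, CXCL1, CXCL8, CDH1, EPCAM, VIM, FN1, CCL2, CSF1, IL6 and CD274, the 14 approved genes with the largest log2 ratio in each direction among those counted, and up to 4 members of each list with the largest absolute ratio. Other list members are named as examples, chosen after their values were seen. Pseudogenes, numbered loci, microRNAs, XIST and Y-linked genes were left out of the naming. Lists of 22 melanocyte and 19 basal-type breast line markers were written after the values of the planned lists were seen and before the values of most of their members were looked up.

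The size rule was tested on simulated data for this comparison, with Poisson counts drawn for 16085 genes and loci. It recovered 81 of 100 genes changed 2.5-fold and 97 of 100 changed 4-fold, and counted 2 of 11780 unchanged genes. Both simulated libraries were drawn from the shCtrl values with counting error alone and no spread between libraries or cultures. The 2 of 11780 is therefore not a rate of false counts for the real pair. There the read interval excluded 1 for 49.3% of measured genes. Alternatives were a pseudocount of 0.1, other scalings (median ratio, TPM, edgeR 4.0.16 TMM and DESeq2 1.42.0 size factors on rounded counts), other filters and folds, and other random lists. Expected counts allowed the edgeR and DESeq2 scalings, but no dispersion can be estimated from 1 library per group, so neither test was run. The DESeq2 size factors were 1 for both libraries, so that scaling left the rounded counts as they were. Exon overlaps between genes were taken from GENCODE release 29. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and R 4.3.3.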

Results

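Expression was measured in 1 shCtrl library and 1 shZEB1 library, both from cells labelled as MDA-MB-231. The shCtrl library held 8740584 assigned reads over 15365 listed genes and loci, and the shZEB1 library 8441491 reads over 15447. FPKM reached 1 for 11836 genes in shCtrl and 12020 in shZEB1. Neither group had a replicate, so every difference below is between 2 libraries, and no spread between cultures stands behind it. Intervals are 95% exact binomial intervals and cover counting error only.

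Both libraries held abundant transcripts of the melanocyte lineage, which the label of a breast carcinoma line does not name. PMEL, a structural protein of melanosomes, had an FPKM of 703 in shCtrl and 405 in shZEB1. SOX10, a neural crest transcription factor, had 175 and 171, and TYR, the first enzyme of melanin synthesis, had 154 and 128. Of 22 melanocyte and melanoma markers, 18 had an FPKM of at least 10 in both libraries, and their median FPKM was 51.8 in shCtrl and 54.9 in shZEB1. Markers of basal-type breast lines were lower, with a median FPKM of 3.13 and 4.21 over 19 genes. Of these 19, 6 in shCtrl and 7 in shZEB1 had an FPKM of at least 10. EGFR had 0.52 and 0.65, KRT7 0.74 and 1.67, and the tissue factor gene F3 0.87 and 1.82, while AKR1B1 had 134 and 113, CAV1 46.6 and 44.0, KRT18 40.5 and 58.7 and PLAUR 38.9 and 31.5. KRT19 was in neither file. Both marker lists were written after the planned lists had been examined, and 9 of the 19 breast markers are also in planned lists. Another of the breast markers was ZEB1, the gene targeted by the knockdown, with an FPKM of 0.88 in shCtrl and 0.31 in shZEB1. All comparisons below are therefore between libraries of cells whose line label was not matched by their marker genes.

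**Figure D1:**
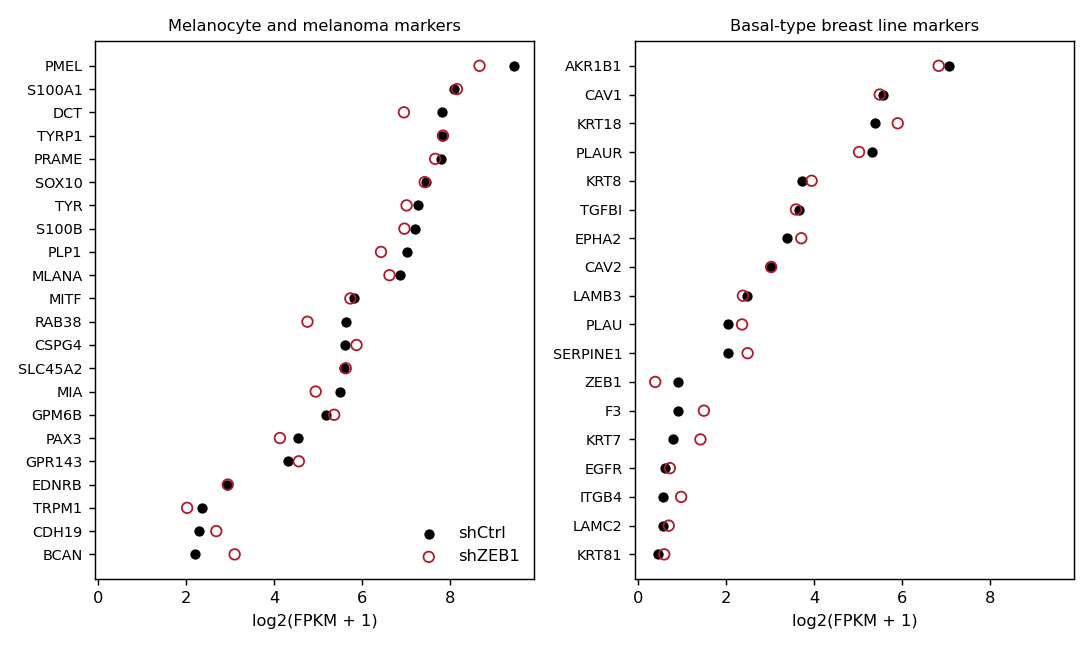
FPKM of melanocyte and melanoma markers (left) and basal-type breast line markers (right) in the shCtrl (filled) and shZEB1 (open) libraries, as log2(FPKM + 1). PMEL lies at the top of the left panel with FPKM of 703 and 405, while EGFR on the right lies at 0.52 and 0.65.

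ZEB1, the targeted gene, was lower in the library labelled as its knockdown. It (Entrez Gene 6935) spans chr10:31318417-31529804 on hg38. Its FPKM was 0.88 in shCtrl and 0.31 in shZEB1, a 2.84-fold lower level that rested on 46 and 15 reads. The read ratio was 0.338 (interval 0.175 to 0.616). ZEB1 was scarce in both libraries: only 21.9% of the genes listed in shCtrl had a lower FPKM. With FPKM below 1 in both, ZEB1 was outside the set of measured genes, and its log2 ratio with the pseudocount of 1 was -0.52. Its exons overlap those of the antisense gene ZEB1-AS1, whose reads cannot be told apart without strand. ZEB2, its paralog, was far more abundant, with an FPKM of 16.3 in shCtrl and 11.3 in shZEB1 (read ratio 0.697, interval 0.640 to 0.760).

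The series asked which genes of the cancer cells link ZEB1 to the M2-like state of tumour macrophages, and its title names CXCL1, a chemokine that acts on CXCR2. CXCL1 (Entrez Gene 2919, chr4:73869393-73871308) was 2.13-fold lower in shZEB1. Its FPKM was 11.6 in shCtrl, from 114 reads, and 5.44 in shZEB1, from 52 reads. The read ratio of 0.472 (interval 0.333 to 0.661) excluded equal levels as far as counting error goes, but the log2 ratio of -0.97 missed the size rule. It passed the threshold of -1 with a pseudocount of 0.1 (-1.08) and on counts with the edgeR or DESeq2 factors (-1.12 with each). With the median ratio and with TPM it missed the threshold. CXCL8, the neutrophil attractant of the same family, was 4.29-fold lower, at 11.6 against 2.70 FPKM (interval of the read ratio 0.160 to 0.335). CXCL2 had 17 reads and 12 reads, and its interval included 1. These 3 were the measured members of 7 CXCR2 ligands, with a median log2 ratio of -0.97, and 15 of 10000 matched random lists had a median as low. That median is the value of CXCL1 itself, so its place is not separate evidence on the family. Matched on length too, 120 of 10000 were as low, and without the FPKM minimum the median was -0.33 over 5 genes (155 of 10000).

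Chemokines outside this family showed no common direction. CX3CL1, a membrane-bound attractant of monocytes and T cells, had an FPKM of 4.78 in shCtrl and 9.37 in shZEB1. CCL5 had 19.8 and 26.6, CCL28 had 17.7 and 12.6, and the intervals of CXCL16 and CCL20 included 1. The median log2 ratio of the 5 measured members was 0.02, and 0 of them met the size rule. CCL2, the classical monocyte attractant, had an FPKM of 0.98 from 6 reads in shCtrl and 0.17 from 1 read in shZEB1, with an interval of 0.00375 to 1.42 that included 1.

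Several secreted factors that act on myeloid cells were lower in shZEB1. CSF3, the granulocyte colony-stimulating factor, was 4.18-fold lower (15.1 against 3.61 FPKM). VEGFA, the angiogenic factor, was 2.40-fold lower (35.8 against 14.9). IL6 was listed with 12 reads in shCtrl and was not listed in shZEB1, and IL1B had 18 reads and 1 read (interval of the ratio 0.00138 to 0.364). Of 20 measured members, 5 were counted as lower, among them PTGES of prostaglandin synthesis, and 0 as higher. The interval excluded 1 for 13 members, 10 lower and 3 higher. The higher ones were PROS1 (34.5 and 46.6 FPKM), WNT5A (2.92 and 4.22) and HMGB1 (250 and 277). CSF1, the macrophage colony-stimulating factor, had an FPKM of 2.04 and 1.73, and its interval included 1. TGFB1 had 13.4 and 11.7 and MIF 823 and 805. The list median was -0.17, with 149 of 10000 random lists as low. It lay within the random range when FPKM of at least 5 was required (464 of 10000) or FPKM of at least 1 in both libraries (639 of 10000).

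Across all genes the libraries were close. The correlation of log2(FPKM + 1) over the 12274 measured genes and loci was r = 0.975 (Spearman rho 0.974), across genes, which are not independent replicates. The size rule counted 115 as higher and 198 as lower in shZEB1. With a pseudocount of 0.1 the counts were 311 and 294, with TPM 236 and 227, and with counts scaled by edgeR 297 and 326, so the surplus of lower genes depended on the measure. Assembled loci, together with identifiers not matched to a symbol, made up 64 of the higher and 45 of the lower ones, against 751 of all measured. Genes with approved symbols, read-through genes left out, came to 45 higher and 151 lower. The read interval excluded a ratio of 1 for 6051 of the 12274, a share of 49.3%, with 3425 higher and 2626 lower.

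**Figure D2:**
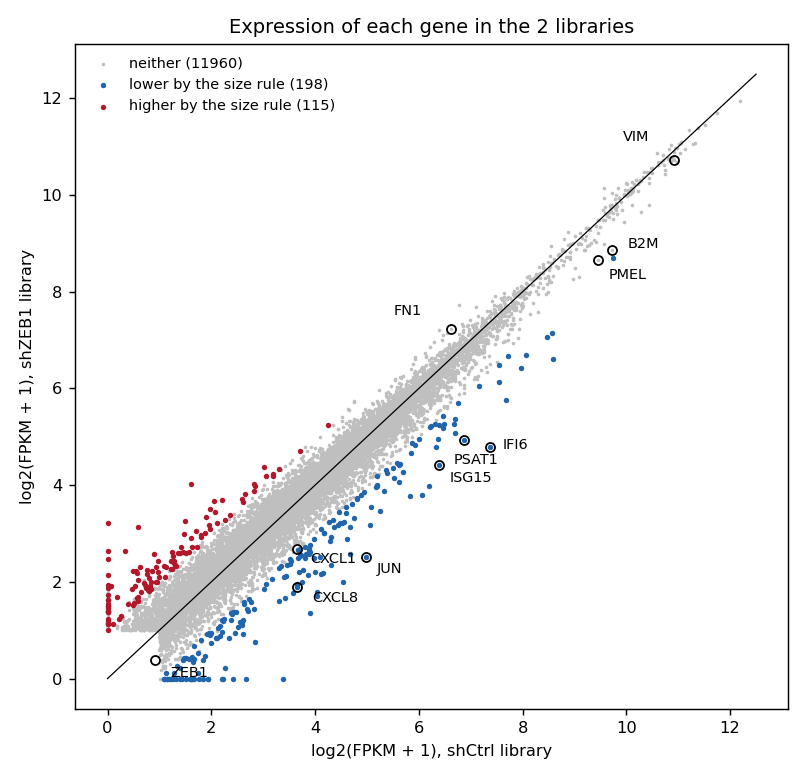
Each point is a gene or locus with FPKM of at least 1 in either library, at log2(FPKM + 1) in shCtrl (x axis) and shZEB1 (y axis), and the line marks equal levels. Blue points are the 198 counted as lower and red points the 115 counted as higher; circles mark named genes, with ZEB1 below the FPKM minimum.

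Of the 14 approved genes that lay lowest in shZEB1, 5 were members of the interferon-stimulated list. IFI6 was 6.17-fold lower (165 against 26.7 FPKM), BST2 (tetherin, which holds viruses at the cell surface) 8.97-fold and IFITM1 6.77-fold. OAS2, a sensor of double-stranded RNA, had 105 reads in shCtrl and 5 in shZEB1, and ISG15 was 4.08-fold lower. Outside that list were the transcription factor gene JUN (30.7 against 4.75 FPKM), CHAC1, which degrades glutathione (15.4 against 2.48), and LAP3, a leucine aminopeptidase (72.2 against 14.9). MRPS33 of the mitochondrial ribosome was 4.39-fold lower and SLAMF9 8.76-fold. SAA1, an acute-phase protein gene, had 18 reads in shCtrl and was not listed in shZEB1. MTPN, GPR75-ASB3 and SERF1A were also listed only in shCtrl, with 319, 62 and 19 reads. These 4 genes are uncertain, since SAA1 has the similar copy SAA2, MTPN shares its transcript with LUZP6, GPR75-ASB3 is a read-through gene, and SERF1A has the near-identical copy SERF1B.

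The approved genes that lay highest in shZEB1 had FPKM of at most 19.9 in either library. BFSP1, a filament protein of the lens, was 4.73-fold higher (1.81 against 8.57 FPKM), and ITGA10, an integrin collagen receptor, 9.23-fold (0.40 against 3.69, from 18 and 160 reads). SLC9A3, a sodium-proton exchanger, was 6.92-fold higher, WNK4, a kinase that regulates ion transport, 4.48-fold, and SLC5A3, the myo-inositol transporter, 3.11-fold. PILRA was 3.55-fold higher, MROH6 3.29-fold and SH3D21 6.11-fold. The read-through genes MICOS10-NBL1, RPL17-C18orf32 and TGIF2-RAB5IF had 62, 79 and 32 reads in shZEB1 and 0, 14 and 4 in shCtrl. PABPN1 (2.80-fold) overlaps the read-through gene BCL2L2-PABPN1, TBC1D3 (6.12-fold) belongs to a multicopy family, and YJEFN3 (3.36-fold) shares exons with NDUFA13. Exons of ITGA10, SLC9A3, WNK4, SLC5A3, PILRA and SH3D21 also overlap or resemble those of other genes. Of the 14, only BFSP1 and MROH6 had no such partner, so the division of reads leaves the other values uncertain. The same holds in the other direction for IFITM1, ISG15, TAP1, VEGFA, ICAM1, CEBPB, CD68, CA9, ANKRD37 and IL6.

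Interferon-stimulated genes were lower as a group. All 32 measured members had a negative log2 ratio, 12 were counted as lower and 0 as higher. The interval excluded 1 for 29 of the 32. Besides the genes above, IRF9 (16.7 against 3.54 FPKM) and IRF7 (18.5 against 6.15), transcription factors of the interferon response, were counted as lower. The list median was -0.67 (counting interval -0.81 to -0.61), below all 10000 matched random lists.

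Genes of antigen presentation, most of them of the MHC class I pathway, were also lower together. All 21 measured members lay below 0, and 4 were counted as lower: TAP1, a subunit of the peptide transporter (25.8 against 8.97 FPKM), HLA-E (108 against 51.3), HLA-B (5.49 against 1.64) and the class II gene HLA-DRA with 13 reads and 1 read. B2M, the light chain of MHC class I, was 1.82-fold lower (840 against 462 FPKM). The immunoproteasome subunits PSMB8, PSMB9 and PSMB10 were 1.72-, 1.91- and 1.72-fold lower. The median was -0.77 (counting interval -0.83 to -0.55), below all 10000 random lists. HLA genes are polymorphic and similar to one another, so their separate values are uncertain. Interferon genes and these lists are not independent, since PSMB8, PSMB9 and TAP1 are themselves known to respond to interferon.

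NF-kB target genes were lower in shZEB1 for 19 of 23 measured members. The 6 that met the size rule were BCL2A1, an inhibitor of apoptosis (48.1 against 15.8 FPKM), the adhesion molecule gene ICAM1 (88.5 against 37.5), NFKBIA (29.9 against 13.5) and TNFAIP3 (10.5 against 4.53), both feedback inhibitors, and IL6 and LCN2, which were not listed in shZEB1. NFKB2 was 1.89-fold and RELB 1.85-fold lower, while NFKB1 had 17.7 and 20.8 FPKM. The list median was -0.51 (counting interval -0.66 to -0.41), below all 10000 random lists.

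Genes of the unfolded protein and amino acid responses, held in 1 combined list, were lower in shZEB1 for 26 of 30 measured members. Of the 30, 9 were counted as lower and 0 as higher. The list median was -0.66 (counting interval -0.69 to -0.54), below all 10000 random lists. The lower ones included PSAT1 of serine synthesis (3.90-fold), ASNS, the asparagine synthetase gene (2.56-fold), ATF3 (3.28-fold), CEBPB (2.79-fold) and the cystine transporter gene SLC7A11 (2.34-fold). Other members differed less or lay the other way. HSPA5, the main chaperone of the endoplasmic reticulum, had 186 and 178 FPKM and HERPUD1 61.4 and 39.4, while DNAJB9 had 5.16 and 7.61.

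Immediate early genes, which respond within minutes to growth factors and stress, were lower for 21 of 27 measured members, and 6 were counted as lower. JUN was 6.46-fold lower, FOS 4.04-fold and EGR1 3.12-fold. KLF2, KLF6 and ATF3 were the other 3. DUSP6, a phosphatase that restrains ERK, had 29.7 FPKM in shCtrl and 41.5 in shZEB1. The median was -0.43, below all 10000 random lists.

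Hypoxia and glycolysis genes had a smaller shift, with a median of -0.24 and 1 of 10000 random lists as low. Of 33 measured members, VEGFA, ANKRD37 (13.8 against 4.97 FPKM) and CA9 (31 reads against 1 read) were counted as lower. HK2, the inducible hexokinase, was 1.77-fold lower and ENO2 1.87-fold. Smaller differences were seen for other members, such as GAPDH (1.19-fold lower) and PGK1 (596 and 570 FPKM). The interval excluded 1 for 29 members, of which 23 were lower and 6 higher. PFKFB4 (55.1 and 63.0 FPKM) was among the higher ones.

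Cell cycle and replication genes were slightly higher in shZEB1. Of 40 measured genes, 32 had a positive log2 ratio and 0 met the size rule. CDC25A, a phosphatase that activates cyclin-dependent kinases, was 1.80-fold higher, KIF20A 1.58-fold, TOP2A 1.58-fold and MCM6 1.41-fold, whereas MKI67 had 53.5 and 62.5 FPKM. The median of 0.18 (counting interval 0.15 to 0.22) lay above all 10000 random lists. Cholesterol synthesis genes had a median of 0.03 (-0.05 under either count-based scaling), within the range of random lists, with EBP at 43.7 and 24.7 FPKM and STARD4 at 6.55 and 10.8. TM7SF2, at 7 and 29 reads, was the only member counted as higher.

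Epithelial genes lay within the range of random lists, and so did mesenchymal genes except where FPKM of at least 5 was required (median -0.16, 85 of 10000 as low). CDH1, the E-cadherin gene that ZEB1 is known to repress, was not listed in shCtrl and had 1 read in shZEB1, and EPCAM was in neither file. Of 46 epithelial genes 15 were measured, with a median of 0.18 that 1945 of 10000 random lists matched or exceeded, and 0 met the size rule. CLDN1 (20 and 50 reads), SPINT2 (22 and 41 reads), KRT7 (11 and 24 reads) and KRT18 (40.5 and 58.7 FPKM) lay highest, and for these 4 the interval excluded 1. In all, it excluded 1 for 6 members, 5 higher and 1 lower, the lower one being ERBB3 (45.9 against 36.8 FPKM). Of 51 mesenchymal and matrix genes 35 were measured, with a median of -0.06 inside the random range. CCN1, a matricellular protein gene, was 2.86-fold lower and TIMP3, a protease inhibitor, 2.04-fold lower, while TPM2, a tropomyosin, was higher (12.1 against 25.3 FPKM). FN1, the fibronectin gene, was 1.53-fold higher, VIM had an FPKM of 1946 and 1695, and MMP1 had 28 and 5 reads.

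Ligands and enzymes that restrain T cells or macrophages had a median of -0.09 over 10 measured genes, within the random range, and 0 met the size rule. CEACAM1 had 3.60 FPKM in shCtrl and 8.16 in shZEB1, and IDO1, a tryptophan-degrading enzyme, 2.48 and 3.95. CD276 was 1.57-fold lower (84.3 against 53.8), and PVR had 25.1 and 17.5. CD274, which encodes PD-L1, had 19 and 11 reads, and its interval of 0.258 to 1.33 included 1.

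**Figure D3:**
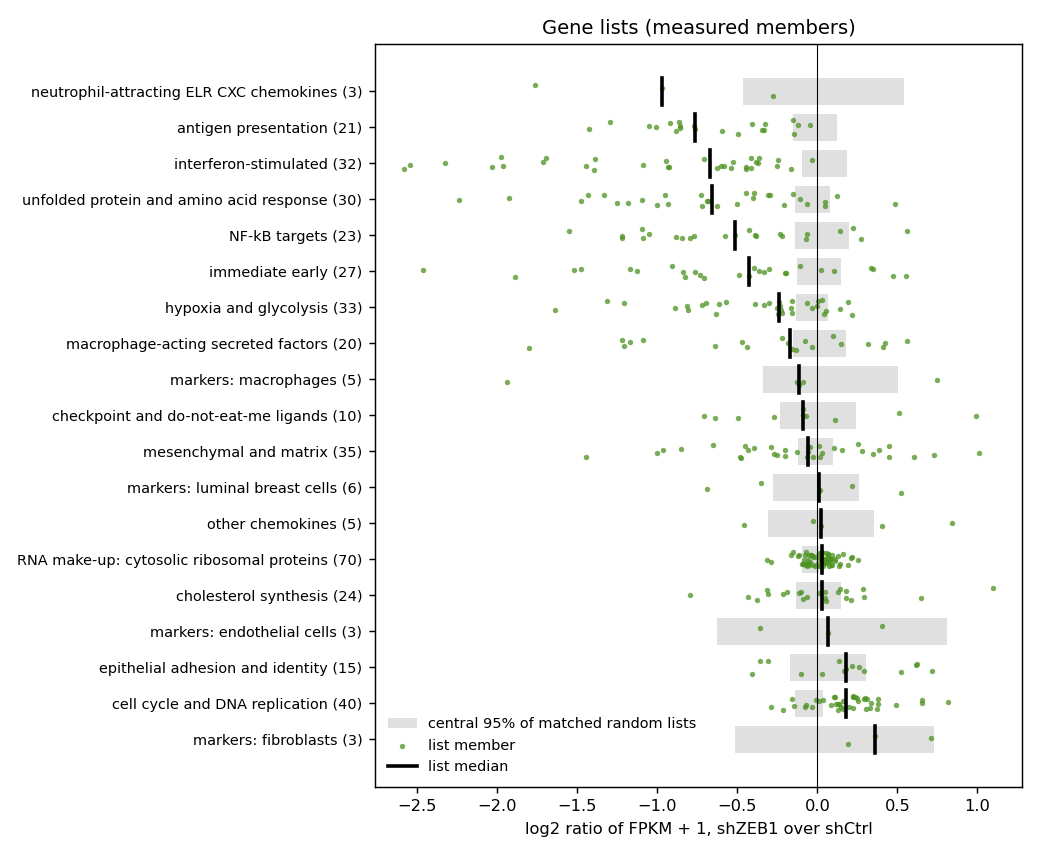
Log2 ratio of FPKM + 1 (shZEB1 over shCtrl) for the measured members of each gene list (points), with the list median (bar) and the central 95% of medians of 10000 expression-matched random lists (grey). The antigen presentation median lies at -0.77 and that of the cell cycle list at 0.18, both outside the grey range.

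Markers of other cell types were few. Of 18 macrophage markers 5 were measured. CD68, a lysosomal protein that other cells also make, was 4.53-fold lower (18.7 against 4.12 FPKM), and LYZ had 29 and 55 reads. The intervals of CORO1A, FCER1G and LAPTM5 included 1, and PTPRC, CD163 and TYROBP were in neither file. Fibroblast markers (3 of 14 measured, LUM, MFAP5 and FAP, all at an FPKM below 2), endothelial markers (3 of 12, ERG, ESAM and FLT1) and luminal breast markers (6 of 20) had medians of 0.36, 0.07 and 0.01, all within their random ranges. In the luminal list, XBP1 had 91.2 and 56.1 FPKM, MLPH 11.6 and 8.86 and KRT8 12.2 and 14.4. The 70 cytosolic ribosomal protein genes had a median of 0.03, which was -0.01 under either count-based scaling. This was above the central 95% of matched random lists (60 of 10000 as high), though not of unmatched ones. Their extremes were RPS7 (1104 and 889 FPKM), RPS28 (601 and 491), RPS3A (1016 and 1213) and RPL27A (194 and 225). No mitochondrially encoded gene was listed under its own name. Of the 19 lists with measured members, 8 had a median below and 2, the cell cycle and ribosomal protein lists, above the central 95% of random lists, where 0.95 would be expected if lists were random draws.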

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

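The tests in this part on the melanocyte markers, on the read-through genes, on scaling and on the culture were chosen after the results were seen. The test on gene length was chosen before, with its bound set after the list medians were known.

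Genes outside the planned lists carried a strong signal: 22 melanocyte and melanoma markers had a median FPKM of 51.83 in shCtrl and 54.88 in shZEB1. For a small admixture of melanocytic cells in a breast line, their median FPKM was predicted to lie below that of 19 basal-type breast markers. It exceeded that median by 13.0 times in shZEB1 and by 16.6 times in shCtrl, which argues against a small admixture. The ratio compares different genes whose levels in pure cells were not known, so it does not give a share of cells. Induction by the knockdown is argued against too, since the median log2 ratio of the markers was -0.11. A candidate explanation is that the sequenced cells were mainly of melanocytic type, so that the line label does not describe them: 18 of the 22 markers had an FPKM of at least 10 in both libraries, and PMEL ranked 110th of the genes in shCtrl. Open remain which line this would be and whether some breast cells were present, since no genotype and no reference profile of MDA-MB-231 was analysed here.

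The lists of 5 groups (interferon-stimulated, antigen presentation, NF-kB targets, amino acid response with unfolded protein, and immediate early) were all lower in shZEB1. The highest of the 5 list medians under the 4 other scalings was -0.41. These scalings could hardly have moved it, since they left the median of all measured genes between -0.011 and 0.075. For all 5 lists, 0 of 10000 matched random lists were as low under each scaling. This adds no support, since a common factor moves a list and its random lists alike. For the same reason, a common factor alone would not set a list below its matched random lists. A trend with gene length exists in these libraries (Spearman rho 0.23 between length and log2 ratio across genes). It is argued against as the cause, since 0 of 10000 random lists matched on both expression and length were as low for any of the 5. With 1 library per group, an effect of the hairpin vector or of the state of the culture at harvest, such as density or time since feeding, cannot be told apart from an effect of ZEB1, which the design names and which stays untested.

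The size rule counted 6 read-through genes as higher or lower. A different division of reads between overlapping gene models would leave the sum of the gene and its parts level. For 3 of the 6 the read-through gene held under 10% of the summed reads, so their sums decide nothing. For the other 3 the sums had a median absolute log2 ratio of 0.42: JMJD7-PLA2G4B lay at 0.66, GPR75-ASB3 at 0.42 and ARMCX5-GPRASP2 at 0.07. The last sum holds ARMCX5 alone as a part, since GPRASP2 was not listed in either library. The absolute value hides a direction. GPR75-ASB3 itself fell from 62 reads to 0, while its sum rose from 180 to 232 reads. That sum therefore does not speak for a lower level of the locus in shZEB1. The division of reads therefore cannot be told apart from a difference in these genes with so few of them, and no biological explanation was tested.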

How the results depend on the processing

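No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The 2 restrictions to approved symbols were chosen after seeing the data. The counts of genes by size depended on the settings. Higher and lower counts were 115 and 198. The higher count became 311 with a pseudocount of 0.1 (294 lower), 236 with TPM (227 lower), 44 with FPKM of at least 5, and 52 with FPKM of at least 1 in both libraries. Higher and lower were 297 and 326 with edgeR TMM, 313 and 326 with DESeq2 size factors, 611 and 664 at 1.5-fold and 7 and 17 at 4-fold. Approved symbols alone gave 45 higher genes, and those without exon overlap 20 higher and 78 lower. The other settings kept both counts within 1.5 times. ZEB1 had a log2 ratio of -1.56 with edgeR TMM and -1.55 with DESeq2 size factors, since a pseudocount of 1 FPKM is large beside its level, and -1.26 with a pseudocount of 0.1. CXCL1 lay between -1.12 and -0.98 under the 5 other scales, past -1 in 3 of them. The correlation of the libraries was 0.969 at FPKM of at least 5 and 0.958 with log2(FPKM + 0.1). All 5 scales put 8 lists below and 2 above the random range, and moved the median of all measured genes by under 0.1. A common factor moves a list and its random lists alike, so the scalings among them could hardly have changed these places. With edgeR TMM and DESeq2 size factors in turn, medians were -0.83 and -0.83 for interferon-stimulated, -0.85 and -0.85 for antigen presentation, -0.71 and -0.71 for unfolded protein and amino acid, -0.53 and -0.53 for immediate early, -0.28 and -0.28 for hypoxia, 0.13 and 0.14 for cell cycle, -0.13 and -0.13 for mesenchymal and -0.055 and -0.050 for cholesterol genes. The ribosomal protein median reversed to -0.011 and -0.0060, was 0.0068 with the median ratio and 0.080 with TPM. TPM gave 0.23 for cell cycle and -0.19 for hypoxia, and a pseudocount of 0.1 gave -0.77 for interferon-stimulated genes. Without a filter the epithelial median was 0.046, that of CXCR2 ligands -0.33 and that of antigen presentation -0.55. At FPKM of at least 5, CXCR2 ligands gave -1.37, mesenchymal genes -0.16 (85 of 10000 random lists as low) and macrophage markers -1.03 over 2 genes. The macrophage-acting factors left the low range at FPKM of at least 5 (464 of 10000) and at 1 in both libraries (639 of 10000). Macrophage markers lay below the range without a filter (105 of 10000) and at FPKM of at least 5 (89 of 10000), and ribosomal protein genes lay within it against random lists not matched on expression. The cause of these shifts was not tested unless stated. Depth limits genes with few reads, such as ZEB1, IL6, CCL2 and CD274, with at most 46 in either library.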

Other observations

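All tests in this part were chosen after the data were seen, except the description of annotated terms, which was planned. The melanocyte markers did not move alike between the libraries. PMEL, DCT (a melanin synthesis enzyme) and RAB38, which carries cargo to melanosomes, had FPKM of 703, 225 and 48.6 in shCtrl and 405, 123 and 26.1 in shZEB1, and their intervals excluded 1. SOX10 (175 and 171), MITF (55.1 and 52.2) and TYRP1 (223 and 228) had intervals that included 1. BCAN, a proteoglycan, had 3.59 and 7.60. Of the 22, 10 were lower and 4 higher beyond counting error, 0 met the size rule, and the list median of -0.11 lay within the range of random lists.

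The deposited files pair genes with Gene Ontology terms, of which 1404 had 10 to 200 measured genes. For 18 terms, 0 of 1000 expression-matched random lists were as low, and for 10 terms 0 of 1000 were as high. The terms farthest below included those of interferon, MHC class I and vesicle or endoplasmic reticulum membranes, with the interferon-gamma-mediated signaling pathway at a median log2 ratio of -0.86 over 21 genes and the type I interferon signaling pathway at -0.90 over 18. The farthest above included chromosome segregation and DNA repair, with mitotic sister chromatid segregation at 0.28 over 33 genes and DNA repair at 0.13 over 122. Terms overlap in genes.

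NAMPT, the rate-limiting enzyme of NAD salvage, had an FPKM of 204 in shCtrl and 53.3 in shZEB1, from 8102 and 2056 reads. ATP5MF of the ATP synthase had 385 and 97.2, but its exons overlap those of ATP5MF-PTCD1. Both were named after their values were seen.

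Long genes lay higher in shZEB1 than short ones. The median log2 ratio of approved genes was -0.07 in the shortest of 4 equal groups by transcript length and 0.12 in the longest. No cause was tested.

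No mitochondrially encoded gene had its own name, but 2 loci assembled by the authors and described as NADH dehydrogenase had FPKM of 2568 and 2016 in shCtrl and 2146 and 1641 in shZEB1.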
